A study of Homo sapiens with 4 samples.

How the data were processed

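ATAC-seq peak lists of 4 libraries of the OVSAHO cell line were used, 2 of test cells and 2 of control cells, with the groups and replicate numbers taken from the labels. Per the labels, DNA was tagmented and libraries were made with a commercial ATAC-seq kit. The submitters' processing notes name cutadapt 3.2, Bowtie2 2.3.5.1, deepTools 3.5.1, Picard, MACS2 2.2.7.1 and edgeR 3.34.1 with the hg19 build, without stating the role of each in the sources used here. Each library had a narrow and a broad peak list, 8 lists in all. Peaks were called with MACS2 2.2.7.1 in each library separately, per the file headers, so replicates were never pooled. Per the file headers, calling used paired-end fragments, no control sample, all duplicates, an effective genome size of 2.7e+09, a q threshold of 0.05 and a regional background range of 10000 bp. Narrow peaks were called on nucleosome-free fragments and broad peaks on all fragments, both from alignments whose file names in the headers mark them as shifted for the transposase, per the file headers.

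The deposited pileup is a coverage signal per peak, the number of fragments over the peak. The deposited p and q of a peak are on the −log10 scale. The deposited fold enrichment is a ratio of the pileup to the local background of the same library, per the file headers. These are the authors' own values for each peak. None is normalized between libraries, so they served here to describe, rank or filter peaks within a list. A deeper library, or one with a larger share of short fragments, can pass the q threshold at weaker sites, and with duplicates kept, repeated copies of a fragment add to the pileup. Without a control sample, repeats that gather reads in every library are called as peaks.

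Coordinates are 1-based on hg19. Main results used chromosomes 1 to 22 and X. Peaks of the 4 libraries were merged where they shared 1 bp or more, and a region was test-only or control-only where both libraries of that group and neither of the other had a peak. Group means of peak numbers were compared with an exact two-sided permutation test over 6 assignments, whose smallest p is 0.333. Overlap of libraries was measured as the Jaccard index of bases. Shares have 95% exact (Clopper-Pearson) intervals, which cover counting error only. Shares of regions in dense windows (1 Mb with 5 or more regions called in all 4 libraries) and on each chromosome were compared with Fisher's exact two-sided test and Benjamini-Hochberg adjustment. Regions to name were chosen by a rule fixed before the data were examined. It takes the 10 per direction with the highest score, the smaller of the 2 libraries' percentiles of fold enrichment within their own lists.

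Alternatives fixed before the data were examined were a −log10 q of 5 or more, equal list lengths, an overlap of 50% of the shorter peak, merging of peaks within 100 bp, all contigs, leaving out each library and a replicate block. Leaving out dense windows and dividing peak numbers by fragments were added after the data were seen. The local background of a peak was recovered as (pileup + 1) divided by fold enrichment, minus 1, and summarised as medians over bins of 5 Mb with 3 or more narrow peaks. Peaks in dense windows were left out of it, a choice made after values with them had been seen. The merging of regions was tested on simulated data, where 4000 of 4000 simulated regions were assigned to the right libraries in each peak type. Simulated regions stood well apart, with peaks of nearly the same centre and width, so crowded or partly overlapping peaks were not tested. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Planned analyses of promoters, of genes and gene lists and of sequence motifs were not run, because an hg19 gene annotation and genome were not used here, and regions are named by position.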

Results

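Open chromatin was profiled by ATAC-seq, in which a transposase cuts and tags accessible DNA, in OVSAHO, an established ovarian cancer cell line. Per the labels, the test cells carried stably raised SMARCA2 and a knockdown of SMARCA4, and the control cells were wild type. SMARCA2 and SMARCA4 are the alternative ATPase subunits of SWI/SNF complexes, which move nucleosomes. Both groups were kept in carboplatin, a platinum drug that crosslinks DNA, at 25 µM for 2 days, so no library shows the cells without the drug. Each group had 2 libraries, named here test 1, test 2, control 1 and control 2. Expression of SMARCA2 and SMARCA4 was not analysed here, so the labels of the groups were not checked against those genes. The labels do not say that the replicates were separate cultures, so p-values from tests between libraries measure only the spread between these samples, which may be technical. Fisher's tests count regions, which are not replicates, and measure no spread between samples.

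Depth was uneven. Per the file headers, the narrow peaks rested on 6146272 nucleosome-free fragments in test 1, 6885374 in test 2, 15828837 in control 1 and 7531794 in control 2. The broad peaks rested on 22432549, 23596152, 31515662 and 25452784 fragments in the same order. Nucleosome-free fragments made up 50.2% of the fragments of control 1 and 27.4% to 29.6% in the other 3 libraries. The mean fragment size of all fragments was 131 bp in control 1 and 178, 179 and 182 bp in test 1, test 2 and control 2.

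The first comparison asked whether the change of SMARCA2 and SMARCA4 went with more or fewer accessible sites. On chromosomes 1 to 22 and X, test 1 had 3402 narrow peaks, test 2 had 4171, control 1 had 10360 and control 2 had 5442. The control mean was 7901 ± 3478 and the test mean 3787 ± 544 (SD, n = 2 per group). Both control libraries lay above both test libraries, but the control SD was close to the difference of 4115 peaks. An exact two-sided permutation test gave p = 0.333, the smallest p that 2 against 2 libraries allow. Per 1000000 fragments the groups lay closer, at 689 ± 48.1 narrow peaks in control and 580 ± 37.0 in test libraries, a ratio of 1.19 against 2.09 for the numbers themselves (SD, n = 2 per group). Broad peaks numbered 8895 in test 1, 13941 in test 2, 18484 in control 1 and 13353 in control 2, a control mean of 15919 ± 3628 against a test mean of 11418 ± 3568 (SD, n = 2 per group, exact two-sided permutation p = 0.667). Per 1000000 fragments these were 556 ± 43.8 and 494 ± 137 broad peaks, a ratio of 1.13 against 1.39. The rates were added after the data were seen. Without control 1 the difference in narrow peaks was 1656 and in broad peaks 1935. Among peaks with a deposited −log10 q of 5 or more, the broad difference changed sign, to -236.5.

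A smaller share of peaks was strong in control 1 than in any other library. A −log10 q of 5 or more was reached by 25.6% of the narrow peaks of control 1 (95% exact interval 24.8 to 26.5), against 45.2% (43.5 to 46.9) in test 1, 39.1% in test 2 and 41.7% in control 2. In broad peaks the shares were 5.33% in control 1, 32.1% in test 1, 14.3% in test 2 and 25.4% in control 2. In number, control 1 still had the most narrow peaks at that threshold, 2654 against 1537 in test 1, 1629 in test 2 and 2267 in control 2. It had the fewest broad ones, 985 against 2857, 1991 and 3390. Of the narrow peaks of control 1, 42.8% lay in a broad peak of the same library, against 71.1% in test 1, 60.9% in test 2 and 67.1% in control 2. These intervals cover counting error only.

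**Figure D1:**
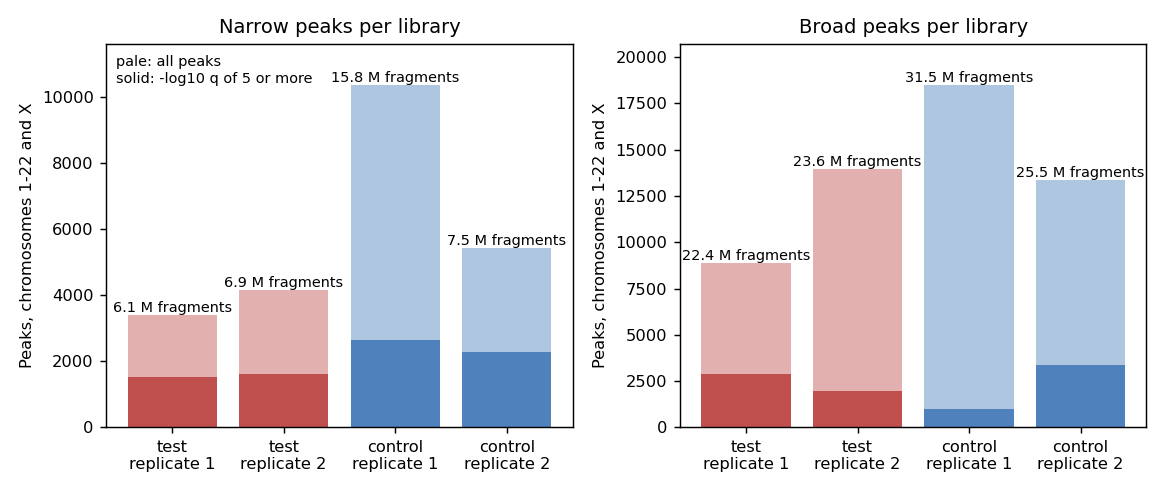
Peaks per library on chromosomes 1 to 22 and X, narrow peaks on the left and broad peaks on the right, with test libraries in red and control libraries in blue; pale bars are all peaks, solid bars those with −log10 q of 5 or more, and the fragments behind each list stand above its bar. Control 1 had the most peaks of both kinds, 10360 narrow and 18484 broad, of which 25.6% and 5.33% reached the stricter threshold.

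The second comparison asked whether libraries of a group shared their accessible regions more than libraries of different groups. They did not by more than the spread between pairs. Test 1 and test 2 had a Jaccard index (shared bases over the union) of 0.271 in narrow peaks, but test 1 reached 0.265 with control 2 and test 2 reached 0.248 with control 2. Control 1 shared little with any library, at 0.0822 with test 1, 0.111 with test 2 and 0.0916 with control 2. The mean was 0.181 ± 0.127 within groups (SD, 2 pairs) and 0.177 ± 0.0933 between groups (SD, 4 pairs). In broad peaks the highest index was 0.360, between test 1 and control 2, and the means were 0.183 ± 0.150 within and 0.209 ± 0.133 between groups. Pairs share libraries, so no test was run. Without control 2 the within-group excess in narrow peaks rose to 0.174, and without test 1 it was -0.0878. Peaks shifted at random 100 times along their chromosomes overlapped in at most 21 narrow peaks of a pair, where the real pairs shared 872 to 1949.

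Merging the narrow peaks of the 4 libraries gave 17554 regions, of which 14159 (80.7%) were called in a single library and 8766 in control 1 alone. A set of 678 regions was called in all 4 libraries. The strongest lay on chromosome 17 at 22020676 to 22020810, with the authors' fold enrichment at 88.2 in test 1, 91.9 in test 2, 62.6 in control 1 and 96.8 in control 2. Others lay on chromosome 2 at 149639298 to 149639412 and on chromosome 13 at 110076475 to 110076676. Since artefact-prone regions were not screened out here, a high fold enrichment need not mean open chromatin. Of the 678 regions, 408 (60.2%) fell in 34 windows of 1 Mb that each held 5 or more of them, named dense windows here. The fullest were chromosome 10 from 42000001 to 43000000 with 53 regions, chromosome 4 from 49000001 to 50000000 with 42 and chromosome 2 from 92000001 to 93000000 with 29, all near centromeres in hg19. Dense windows were defined after the data were seen.

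The third comparison asked which regions were accessible in the test cells and not in the control cells. A narrow peak in both test libraries and neither control library marked 220 regions. The highest ranked lay on chromosome 12 at 56694145 to 56694307, with a fold enrichment of 12.1 in test 1 and 9.92 in test 2. Next came chromosome 9 at 16705281 to 16705503 (9.08 and 9.04), chromosome 21 at 34915130 to 34915275 (8.58 and 10.3), chromosome 12 at 49463756 to 49463877 (10.5 and 7.66) and chromosome 5 at 271463 to 271751 (7.78 and 7.35). The other 5 named regions lay on chromosome 21 at 35288087 to 35288247, chromosome 2 at 74425603 to 74425764 and at 110371594 to 110371819, chromosome 9 at 6681255 to 6681365 and chromosome 10 at 74856745 to 74856890. All 10 overlapped a broad peak of control 2, and 1 of them a broad peak of control 1. Of the 220 regions, 183 (83.2%) overlapped a broad peak of a control library, 181 of them one of control 2. Just 6 were called in the test libraries alone in both peak types, at chromosome 5 from 32852708 to 32852820 and from 148381730 to 148381931, chromosome 6 from 49430917 to 49431036, chromosome 10 from 63388711 to 63388889, chromosome 11 from 14443979 to 14444133 and chromosome 3 from 93698820 to 93698933. These 6 were singled out after their values were seen. Leaving out a library gave 1807 regions without test 1, 1335 without test 2, 278 without control 1 and 890 without control 2. The stricter threshold gave 83, and lists of equal length gave 277.

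Control-only regions, with a narrow peak in both control libraries and neither test library, numbered 219. The highest ranked lay on chromosome 10 at 42815345 to 42815441, with a fold enrichment of 22.2 in control 1 and 23.3 in control 2, and on chromosome 9 at 66843809 to 66843912, with 22.9 and 15.7. Both were in dense windows. Outside dense windows came chromosome 11 at 48946528 to 48946607 (14.5 and 14.4), chromosome 3 at 197895780 to 197895926 (11.3 and 12.2), chromosome 2 at 159440712 to 159440789 (16.8 and 11.8) and chromosome 1 at 6253578 to 6253660 (13.8 and 9.95), with further regions on chromosome 22 at 23827853 to 23827926 and chromosome 5 at 32370427 to 32370514. The remaining named regions, on chromosome 18 at 77379310 to 77379522 and chromosome 1 at 121356067 to 121356143, were in dense windows. Of the 10 named regions, 3 overlapped a broad peak of a test library. Those on chromosome 3 and on chromosome 1 at 121356067 overlapped broad peaks of all 4 libraries, and that on chromosome 10 broad peaks of test 2 and control 1. Only 4 of the 10 overlapped a broad peak of a control library, so most of these narrow calls had no broad peak in their own group. Dense windows held 70 of the 219 control-only regions (32.0%) and 1 of the 220 test-only regions (Fisher's exact two-sided test, Benjamini-Hochberg adjusted p = 8.45e-23 over 12 tests). The share went with control 1 more than with the control group: dense windows also held 29.9% of the 77 regions of test 1 and control 1 alone and 18.0% of the 328 of test 2 and control 1 alone, against 1.76% of the 510 of test 1 and control 2 and 1.21% of the 413 of test 2 and control 2. The test compares these libraries, since regions are not replicates. Dense windows were defined by regions that all hold a control 1 peak, and a test-only region must lack one. The test therefore does not measure a group difference apart from control 1. The 12 tests also include comparisons with the regions that define the windows. A broad peak of a test library overlapped 108 of the 219 (49.3%), and broad peaks of both control libraries overlapped 99. Both test libraries had a broad peak at 164 of the 220 test-only regions. Just 17 were control-only in both peak types, among them chromosome 18 at 77379310 to 77379522 and chromosome 1 at 90844565 to 90844759. Leaving out a library gave 263 regions without test 1, 397 without test 2, 2910 without control 1 and 8985 without control 2. The stricter threshold gave 135, and lists of equal length gave 139, so the balance of 220 test-only and 219 control-only regions became 277 and 139 at equal lengths but 83 and 135 at the stricter threshold.

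The same 4 libraries can be split in pairs in 3 ways. The study groups gave 220 and 219 exclusive narrow regions. Pairing test 1 with control 2 and test 2 with control 1 gave 510 and 328, and pairing equal replicate numbers gave 77 and 413. The study groups therefore did not stand out from the other pairings. Of 1626 regions called in both test libraries, control 2 called 1348 (82.9%, 95% exact interval 80.98 to 84.70) and control 1 called 736 (45.3%, 42.8 to 47.7). Of 1902 regions of test 1 and control 2, test 2 called 70.9% (68.8 to 72.9), and of 1939 regions of test 2 and control 2, test 1 called 69.5% (67.4 to 71.6). With every list at 3402 peaks, control 2 called 78.2% and control 1 called 44.7% of the regions of both test libraries, test 2 called 73.8% of those of test 1 and control 2, and test 1 called 75.3% of those of test 2 and control 2. Strong regions of the other 3 libraries that control 1 lacked included chromosome 5 at 93905093 to 93905233, with a fold enrichment of 30.2 in test 1, 30.2 in test 2 and 35.5 in control 2, and chromosome 2 at 88124415 to 88124490, with 27.8, 23.9 and 42.2. Regions prone to mapping artefacts were not screened out here, so these calls need not be open chromatin.

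**Figure D2:**
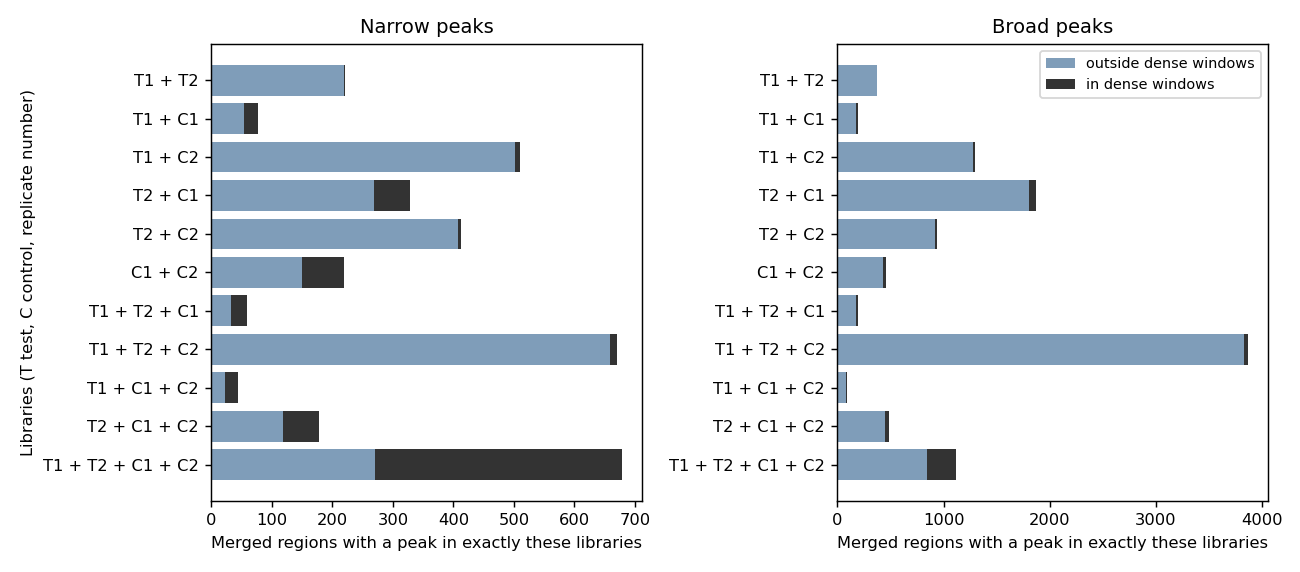
Merged regions by the exact set of libraries with a peak, narrow on the left and broad on the right, for sets of 2 or more libraries (T test, C control, with the replicate number); the x axis counts regions, and dark parts lie in dense windows. Test-only (T1 + T2, 220) and control-only (C1 + C2, 219) narrow regions were fewer than those of test 1 with control 2 (510), and 670 regions were called in every library but control 1.

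Broad peaks, called on all fragments, gave 377 test-only and 456 control-only regions among 36726. The highest ranked test-only regions lay on chromosome 6 at 133135371 to 133135703, with a fold enrichment of 6.79 in test 1 and 4.84 in test 2, chromosome 19 at 8509595 to 8509869 (5.74 and 4.88) and chromosome 12 at 53845614 to 53845884 (6.69 and 4.74). The highest ranked control-only regions lay on chromosome 21 at 15457260 to 15457441, with 16.1 in control 1 and 14.1 in control 2, chromosome 11 at 48817861 to 48818771 (11.7 and 9.06) and chromosome 7 at 61608193 to 61608953 (9.23 and 7.73). The test-only region on chromosome 12 overlapped narrow peaks of both test libraries and of control 2, and the 3 control-only regions each overlapped a narrow peak of test 1. Pairing test 1 with control 2 and test 2 with control 1 gave more exclusive regions than the study groups, 1293 and 1874. Dense windows held 26 of the 456 control-only and 7 of the 377 test-only regions (Fisher's exact two-sided test, adjusted p = 0.00506). This difference of 3.84 percentage points rose to 28.5 at the stricter threshold, with few regions left, and lay between 3.40 and 5.16 in the other alternatives. The other pairs with control 1 were at 9.90% (with test 1) and 3.79% (with test 2), and those with control 2 at 1.55% and 1.61%. A test-only broad region also lacks a control 1 peak, so the Fisher's test here carries the same limit. Test-only counts were 5437 without test 1, 2112 without test 2, 574 without control 1 and 4241 without control 2. Control-only counts were 549 without test 1, 942 without test 2, 5536 without control 1 and 14425 without control 2. The stricter threshold gave 130 test-only and 30 control-only regions, and equal lists gave 460 and 111, so under both there were more test-only than control-only regions, against fewer in the full lists.

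The last comparison asked which chromosomes held the group-specific regions. In narrow peaks, chromosomes 11, 12 and 19 held more of the test-only regions and chromosomes 4 and 18 more of the control-only regions. Chromosome 19 held 24 of 220 test-only and 8 of 219 control-only regions (adjusted p = 0.0328), and chromosome 4 held 2 and 17 (adjusted p = 0.00693). These were the 5 of 23 chromosomes that passed Fisher's exact two-sided test after Benjamini-Hochberg adjustment. Outside dense windows 0 of 23 passed, and 2 (chromosomes 11 and 19) had an unadjusted p under 0.05. The shares of test-only and control-only regions on chromosomes 11, 12 and 19 moved little, from 8.18% and 1.83% to 8.22% and 2.68%, from 8.18% and 2.28% to 8.22% and 3.36%, and from 10.9% and 3.65% to 10.96% and 3.36%, with 149 control-only regions left of 219, so the loss of those 3 calls does not show that dense windows made these differences. On chromosomes 4 and 18 the control-only share fell, from 7.76% to 2.01% and from 4.57% to 2.01%. In broad regions 9 chromosomes passed, and 8 outside dense windows. Chromosome 12 held 33 of 377 test-only and 3 of 456 control-only broad regions (adjusted p = 6.79e-08), and chromosome 20 held 2 and 24 (adjusted p = 0.000267). Chromosomes 11, 16, 17 and X also held more of the test-only regions, and chromosomes 1, 7 and 18 more of the control-only regions. Chromosome 18 was the call lost outside dense windows (Fisher's exact two-sided test, adjusted p = 0.0619). Its test-only and control-only shares moved little, from 0.796% and 3.51% to 0.811% and 3.26%.

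A control-only region must hold a control 1 peak and a test-only region must lack one. The tests of these regions therefore carry the make-up of the control 1 list and do not measure the chromosome differences apart from it. Chromosome 12 held 1.27% of the narrow peaks of control 1 and 2.66% of those of control 2, and chromosome 20 held 6.66% and 4.48%. Shares of whole lists compare control 2 with the test libraries without control 1. In broad peaks chromosome 12 held 2.76% in control 2, 3.99% in test 1 and 3.51% in test 2. Chromosome 18 held 1.92%, 1.21% and 1.33%. On both, the exact interval of control 2 lay apart from those of the test libraries, in the direction of the tests above. Those tests used the same lists, so this is no separate support, and no adjustment was made for the number of chromosomes examined. In narrow peaks on chromosomes 4, 11, 12, 18 and 19 the interval of control 2 overlapped that of a test library. In broad peaks it did so on chromosomes 1, 7, 11, 16, 17, 20 and X.

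**Figure D3:**
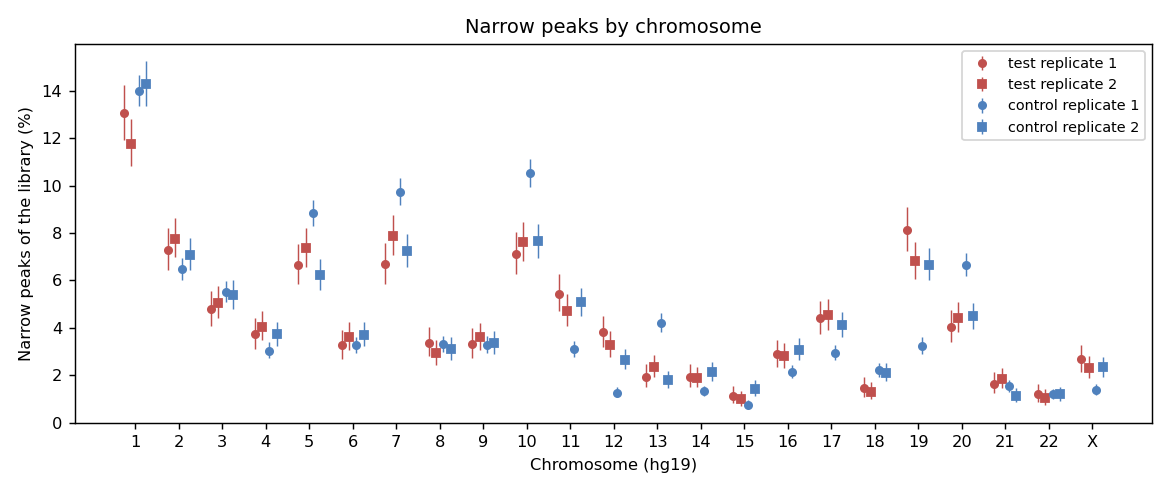
Share of each library's narrow peaks on each hg19 chromosome, in percent, with test libraries in red, control libraries in blue, circles for replicate 1, squares for replicate 2 and bars for 95% exact intervals. Control 1 stood apart on several chromosomes, with 1.27% of its peaks on chromosome 12 and 3.25% on chromosome 19, where control 2 had 2.66% and 6.67%.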

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

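Leaving out dense windows and peaks per 1000000 fragments were chosen only after results were seen, as were the sharing ratio of the pairings and the dense-window shares. The control excess in narrow peaks kept its direction in all 8 alternatives, at 109 peaks per 1000000 fragments and otherwise from 877.5 at the stricter threshold to 6573.5. The broad excess kept it in 7 of 8 (61.9 peaks per 1000000 fragments) and reversed at the stricter threshold, to -236.5, where the list of control 1 fell to 985 peaks. No alternative could pass p = 0.05, since the smallest exact p is 0.333. At the stricter threshold, narrow control-only regions moved to 135, narrow test-only to 83, broad control-only to 30 and broad test-only to 130, from lists made shorter by construction. Equal list lengths moved narrow control-only regions to 139 and broad control-only to 111, with test-only regions at 277 and 460, and give no value for peak numbers. The balance of test-only and control-only regions was 220 and 219 narrow and 377 and 456 broad in the full lists. With equal list lengths it went to the test-only side in both peak types. At the stricter threshold it went to the control-only side in narrow peaks (83 and 135) and to the test-only side in broad peaks (130 and 30). The overlap rule, merging within 100 bp, all contigs and leaving out dense windows kept all 4 counts within 1.5 times.

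Leaving out 1 library, which leaves a group with 1 list and fewer conditions to meet, gave ranges of 263 to 8985 (narrow control-only), 278 to 1807 (narrow test-only), 549 to 14425 (broad control-only) and 574 to 5437 (broad test-only). The difference in peak numbers ranged from 1655.5 to 6573.5 (narrow) and 1935 to 7066 (broad). The mean Jaccard index within minus between groups ranged from -0.0878 to 0.174 (narrow) and -0.139 to 0.189 (broad). With equal lists the narrow value was -0.00758 against 0.00452, both far inside the SD over pairs of 0.0918.

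With the replicate block, pairing equal numbers, the difference was 4114.5 narrow peaks (exact sign-flip p = 0.5, the smallest possible) and 4500.5 broad peaks (exact sign-flip p = 1). Control minus test was 6958 and 1271 narrow peaks, and 9589 and -588 broad peaks. Over the merged regions, peak calls were subtracted between the control libraries and, in the same replicate order, between the test libraries. The correlation of these differences was -0.0187 (narrow) and -0.0786 (broad). It does not measure how much same-numbered libraries overlap. Most merged regions, 80.7% in narrow and 70.4% in broad peaks, were called in a single library. Such regions cannot show libraries deviating together, so whether same-numbered libraries share more than a number stays open. Planned promoter, gene, gene list and motif analyses, with their alternatives, were not run. Depth differs with the library, so a missing call in a library of 6146272 fragments is not evidence of closed chromatin.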

Other observations

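The tests below were chosen only after results were seen, except 3 fixed before their values: recovery by strength of region, the sharing ratio in bins of low background, and the chromosomes of regions shared by test 2 and control 1. Leaving dense windows out of the local background, comparing the regions of test 1 alone with those of test 2 alone, and recovery by strength over all regions of both test libraries, were also chosen after seeing values.

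The local background under the narrow peaks, relative to each library's median over those peaks, was highest on chromosome 20 in all 4 libraries. Calling had no control sample, so this background comes from the library's own fragments around each peak. It can include signal and need not be noise. Chromosome 20 stood at 1.90 ± 0.0574 (SD, n = 4 libraries), followed by chromosome 19 at 1.52 ± 0.0644, and chromosome 15 had the lowest mean, 0.689 ± 0.0576. On chromosome 17 control 1 was at 1.76, while test 1, test 2 and control 2 were at 1.06, 0.995 and 1.03. Of 291 bins of 5 Mb measured in every library, 26 were at 1.5 or more in all 4. Among them were chromosome 20 from 60000001 to 65000000 at 2.60 ± 0.276 and chromosome 17 from 75000001 to 80000000 at 2.04 ± 0.0866. Some other high bins did not agree between libraries. Chromosome 7 from 55000001 to 60000000 was at 16.3 in test 1 and 17.5 in test 2 but 2.65 in control 1 and 2.46 in control 2, medians over 9, 13, 32 and 15 peaks, although each library had 5 to 7 peaks there at 10 or more. Chromosome 6 from 55000001 to 60000000 was at 9.41 in control 1 and 16.6 to 16.7 in the others, over 5 to 12 peaks.

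Control 1 lacked 890 of the 1626 narrow regions called in both test libraries. A smaller number of fragments given to peak calling is argued against by its nucleosome-free fragments, 2.31 times the mean of the others, but copies of fragments were kept in calling and not counted here, so whether control 1 had fewer distinct fragments stays open. Sites closed in the control cells as the whole cause are argued against by control 2, which had a narrow peak in 670 of the 890 (75.3%, 95% exact interval 72.3 to 78.1) and a broad peak in 181 of the other 220, while the 39 regions with no peak of control 2 stay open. A candidate explanation is lower enrichment over background in control 1: of the 929 regions outside dense windows that both test libraries and control 2 shared it called 12.9%, 15.5%, 18.5% and 69.4% from the weakest to the strongest quartile, a difference of 56.5 percentage points between the ends that lies nearly all in the strongest quartile (11.5%, 14.2%, 16.3% and 60.7% over all 1181 regions of both test libraries there). A library may miss weak regions more often for other reasons too, which were not tested.

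The regions of control 1 alone crowded into parts of some chromosomes, above all 5, 7, 10, 13 and 20, with 40.0% of its narrow peaks there. Whether chromatin was open there in the control cells stays open, since control 2, at 27.4%, lay between test 1 at 26.4% and test 2 at 29.6% (a difference of -2.24 percentage points from test 2, with overlapping intervals). Higher local background as the whole cause stays open too. Chromosome 13 was at 0.892 ± 0.0478 of the library median (SD, n = 4 libraries) and below 1 in each. That median was taken over peaks, and the lowest recovered background was close to the average coverage of the genome (0.369 against 0.363 in control 1). A value below 1 can therefore still lie above that average, so chromosome 13 cannot decide the question. The parts of chromosome 13 differed. The bin from 110000001 to 115000000, with 100 regions of control 1 alone, was at 1.52 to 1.99 in the 4 libraries. The bin from 100000001 to 105000000, with 52, was at 0.796 to 0.914. For chromosome 20, at 1.90, higher background also stays open as the cause. Chromosome 19 had the next highest background, 1.52, but 3.25% of the narrow peaks of control 1 against 6.67% to 8.14% in the other libraries. That share is of whole lists. Regions of control 1 alone there numbered 45, 42, 45 and 56 in the bins of 10000001 to 20000000 and 30000001 to 40000000, at 1.41 to 2.23. They numbered 4, 3, 2 and 4 from 40000001 to 60000000, at 0.630 to 1.46, and 12 to 31 per bin elsewhere. Chromosome 19 therefore does not decide the question. Over 5-Mb bins the number of regions of control 1 alone rose with the background of each library (Spearman's rho 0.521 to 0.647, or 0.375 to 0.527 as first computed with dense windows kept), but so did the number of regions that the other 3 libraries shared and control 1 lacked (0.359 to 0.458).

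Test 1 shared exclusive regions with control 2, and test 2 with control 1, more than the study groups did, with a ratio of 0.537 for the study groups over that pairing, and no biological explanation was tested. Parts of high background as the whole cause are argued against by a ratio of 0.624 in the bins below the median (0.538 with dense windows kept). Lower enrichment in test 2 and control 1 may add regions of the kind in control 1 alone to both: those they alone shared lay on chromosomes 5, 7, 10, 13 and 20 by 18.0 percentage points more often than those of test 1 and control 2. Such regions hold control 1 peaks by definition. So do the 54 regions of test 1 and control 1 alone, of which 33.3% (95% exact interval 21.1 to 47.5) lay there. That interval overlaps the 45.4% (39.3 to 51.5) of test 2 and control 1. The regions of test 2 alone also lay there more often than those of test 1 alone, 31.6% (29.3 to 34.0) against 26.0% (23.4 to 28.7). Exchanged labels cannot be told apart from this, since test 2 overlapped control 1 less than test 1 (Jaccard difference -0.160) but control 1 overlapped every library little.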
